A study of Mus musculus with 4 samples.

How the data were processed

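RNA from 4 stages of osteoclast formation in culture was measured on single-channel microarrays, with 1 array per stage. Per the labels, marrow cells of C57BL/6 mice aged 8 to 10 weeks were grown for 3 days with M-CSF at 100 ng/ml, which gave bone marrow macrophages (BMM). RANKL at 100 ng/ml was then added for 2 days to obtain mononuclear pre-osteoclasts positive for TRAP, the tartrate-resistant acid phosphatase used as an osteoclast stain (pOC). A further 2 days with both cytokines gave multinucleated osteoclasts, either on plastic (mOCp) or on slices of dentin, where they resorb the mineralised surface (mOCd). The names and layout of the probe sets and of their controls are those of Affymetrix expression arrays.

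The deposited values were linear signal intensities, 1 per probe set and array, and MAS5 is named in the submitters' processing notes, with no version given in the sources used here. In the deposited table the mean intensity after trimming 2% from each end was 100.0 on every array, so each array had been brought to the same trimmed mean. Such a scaling makes arrays comparable gene by gene, but it removes any difference in total mRNA between stages. MAS5 subtracts a mismatch-based background, which leaves dim probe sets imprecise, and no detection calls were used here. The sources used here do not say whether 1 animal or a pool supplied each RNA, and raw scanner files were not used here.

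The table held 45101 probe sets, of which 64 were manufacturer controls. Probe sets were named through a platform annotation dated 2016. Among the 45037 other probe sets, 34945 carried exactly 1 gene symbol, 932 carried several and were not used to name a gene, and 9160 were not listed there and are unnamed here. Of 34958 probe sets with 1 symbol, controls included, 34754 matched a current mouse gene by Entrez identifier in a RefSeq table of assembly GRCm38.p6, and 0 symbols had to be updated. That table served for names only, and no coordinates are given because the sources used here name no genome build.

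From the intensities the following was computed. On each array, values under the 50th percentile of its non-control probe sets were set to that percentile, called the floor here. Each of 18193 genes was represented by the probe set with the highest mean log2 intensity over the 4 arrays. A gene was counted as higher or lower when the ratio of the floored values was at least 2-fold and the brighter value lay at or above the 75th percentile of its array. Where the dimmer value lay at the floor the ratio is a lower bound and is written as at least N-fold, and no fold is given where both did. Genes eligible for these counts were those whose brighter value reached that percentile.

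The comparisons were pOC against BMM, mOCp against pOC, mOCd against pOC and mOCd against mOCp. With 1 array per group there are no replicates, so no p-value, standard error or test between groups exists, and the number of arrays limits the precision of every value. The remaining guide to measurement error was the disagreement between probe sets of the same gene, taken as the SD of the difference of their log2 ratios divided by the square root of 2. It contains differences between transcripts and leaves out the spread between animals, cultures and arrays.

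For each of 26 gene lists the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean log2 intensity in 20 bins. A list is said to stand apart when its percentile was at most 2.5 or at least 97.5. Floored ratios enter these medians and the figures as they stand, so a median whose middle genes are bounds depends on the floor. The percentile describes these arrays and is not evidence over replicates. Members whose 4 values all lay under the floor counted as not measured, and members without a probe set named for 1 gene were not analysed here. The lists cover osteoclast functions (resorption machinery, cell fusion, RANK signalling with osteoclast transcription factors, repressors of osteoclast formation, podosome and sealing zone, calcium and phosphate transport, V-ATPase subunits, lysosomal proteins, and secreted factors proposed to link osteoclasts to osteoblasts). Others cover macrophage markers, chemokines and cytokines, MHC class II, interferon response, mitotic cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, hypoxia response, and heat shock with immediate early genes. A last set holds markers of other cells that marrow could bring: stromal and osteoblast, neutrophil, erythroid, B, T and NK, dendritic and mast, and endothelial cells.

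Genes named singly were chosen by a rule: the 8 highest and 8 lowest ratios measured above the floor on both arrays of a comparison, the 4 brightest genes on each side that were at the floor on the other array with a ratio of at least 4-fold, any list member, and Cthrc1. Transcripts known only by clone or model names were counted and not named. The groups, comparisons, lists, thresholds, the rule for named genes and 8 processing alternatives were fixed before the data were examined. The alternatives were median scaling over genes above the floor on all arrays, quantile normalization, loess per comparison with a span of 0.4, floors at the 40th and 60th percentiles, no minimum for the brighter array, the mean over all probe sets of a gene, and leaving out suffixed probe sets (_a_at, which match several transcripts of a gene, and _s_at or _x_at, which can match transcripts of other genes). A scaling to 6 hybridisation spike-in probe sets was added after the control probe sets had been seen.

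The counting and list steps were tested on simulated data for mOCp against pOC over 18193 genes, with a noise SD of 0.25 on the log2 scale. They recovered 98.0% of genes simulated 3-fold higher, 92.0% of those simulated at 0.333-fold and 14.0% of those at 1.5-fold. Of unchanged genes 0.48% were counted, and 4.0% of random lists stood apart. Each recovery rate rests on 50 simulated genes. No rate was given for dim genes, so the recovery rates may hold for bright genes only and cannot be carried over to dim ones. The probe-set disagreement of the real log2 ratios in this comparison was 0.419. The simulated SD of 0.25 was added to each array value, so the noise of a simulated ratio is larger than 0.25 and these figures are not directly comparable. The simulated rates may still be better than those on these arrays, above all for dim genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.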

Results

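The data were 4 expression arrays that follow mouse marrow cells from macrophages (BMM) through mononuclear pre-osteoclasts (pOC) to multinucleated osteoclasts kept on plastic (mOCp) or resorbing dentin (mOCd), with 1 array for each and no replicates. The study's title concerns Cthrc1, a secreted collagen triple helix repeat protein, made by osteoclasts in the coupling of resorption to bone formation. The floor lay at an intensity of 12.7 in BMM, 14.5 in pOC, 14.8 in mOCp and 15.8 in mOCd, and the 75th percentile at 87.0, 81.5, 77.8 and 79.1. Of 18193 named genes, 13072 exceeded the floor on at least 1 array and 9047 on all 4. Across genes, which are not independent replicates, Pearson's r of log2 intensity was 0.906 between BMM and pOC, 0.941 between pOC and mOCp, 0.932 between pOC and mOCd and 0.976 between mOCp and mOCd. BMM lay furthest from mOCd, with r of 0.826.

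Cthrc1, measured by 1 probe set, had an intensity of 11.8 in BMM, 4.0 in pOC, 26.4 in mOCp and 179.9 in mOCd. The BMM and pOC values lay under the floor, the mOCp value just above it, and only the mOCd value exceeded the 75th percentile of its array. The study chose this gene, possibly on these arrays, so its direction here is not independent evidence.

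The comparison of pOC with BMM covered 2 days of RANKL, which were also 2 further days of culture. No array holds cells kept for that time with M-CSF alone, so RANKL and time in culture cannot be told apart. Genes of the resorbing osteoclast were far brighter in pOC, while macrophage, interferon and cholesterol synthesis genes were dimmer. Ctsk, encoding cathepsin K, the protease that degrades bone collagen, stood at 8026.2 in pOC against 22.5 in BMM (357-fold higher). Acp5, which encodes TRAP, was 178-fold higher, Mmp14, a membrane matrix metalloproteinase, 73.3-fold, and Mmp9, a secreted one, at least 514-fold. C1qa, a complement subunit made by macrophages, was 80.5-fold lower, and the monocyte chemokine Ccl7 79.2-fold lower.

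Among resorption machinery genes 12 of 15 measured were higher and 0 lower, with a median log2 ratio of at least 2.86, a bound because its middle gene, Itgb3, was at the floor in BMM (percentile 100.0 among matched random lists). They included Car2, the carbonic anhydrase that supplies protons for acid secretion (at least 98.6-fold), the immune receptor Oscar (at least 23.6-fold) and the chloride transporter Clcn7 (3.1-fold). Of 17 V-ATPase subunits 10 were higher (median 1.07, percentile 99.99), from Atp6v0d2 at 162-fold and Atp6v1d at 4.34-fold to Tcirg1 at 2.02-fold, and Atp6v0a1, another form of the subunit that Tcirg1 encodes, was 7.17-fold lower. In the RANK signalling and transcription factor list 9 of 16 were higher (median 1.76, percentile 100.0). Nfatc1, the central transcription factor of osteoclast formation, was 19.5-fold higher, Jdp2 31.4-fold, Prdm1 24.4-fold and the mitochondrial coactivator Ppargc1b 19.8-fold. Repressors of osteoclast formation went the other way, with 6 of 7 lower (median −2.14, percentile 0.01), among them Irf8 at 15.3-fold, Id2 at 7.68-fold and Bcl6 at 4.42-fold. The podosome and sealing zone list had 9 of 18 higher and 2 lower (median 0.71, percentile 99.77), with Cttn, the actin-binding protein cortactin, at least 120-fold and Src at least 16.0-fold higher, and Ptk2b 2.25-fold lower. It no longer stood apart when suffixed probe sets (_a_at, _s_at or _x_at) were left out (percentile 80.49).

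Macrophage markers were lower for 14 of 20 and higher for 0 (median −2.75, percentile 0.0). The Fc receptor Fcgr1 was 34.5-fold lower, the fractalkine receptor Cx3cr1 24.5-fold and Adgre1, which encodes the F4/80 antigen, 4.95-fold, whereas Csf1r, the M-CSF receptor, read 5815.9 in BMM and 4898.6 in pOC. Interferon response genes were lower for 10 of 12 (median −2.59, percentile 0.0), with Ifit2 30.1-fold, Rsad2 16.7-fold and Mx1 at least 16.7-fold lower. Cholesterol synthesis genes were lower for 12 of 14 (median −1.80, percentile 0.0), including Fdft1 at 8.08-fold, Cyp51 at 8.0-fold and Hmgcs1 at 2.33-fold. Ch25h, which makes an oxysterol from cholesterol, was 67.3-fold lower. Oxidative phosphorylation genes were higher for 11 of 20 and lower for 0 (median 1.02, percentile 100.0), such as Uqcrfs1 at 3.12-fold and Ndufs1 at 2.63-fold.

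Cell cycle genes stood apart on the low side without any reaching 2-fold (median −0.38, percentile 0.5, 0 of 22). Lysosomal genes had a median of −0.18 (percentile 0.51) with 4 of 21 lower, among them Lipa at 5.29-fold, and Ctsk higher. This list moved inside the central 95% after quantile or loess normalization. Chemokines and cytokines were split, with 8 of 17 lower, such as Ccl4 at 42.4-fold, and Ccl5 and Il1rn higher at 6.17-fold and 2.06-fold, and the list was inside (percentile 21.28) but stood apart on the low side with the higher floor and without suffixed probe sets (median down to −1.08). The cell fusion list was split too: Dcstamp (103-fold), Ocstamp (at least 153-fold) and Atp6v0d2 were higher, Adam8, Sirpa and P2rx7 between 2.28-fold and 2.45-fold lower, and the percentile was 8.42. Outside the lists, the actin-severing protein scinderin (Scin) was 84.2-fold higher, the cation/proton exchanger Slc9b2 at least 153-fold and the transcription factor Bhlhe40 35.1-fold. Glycolysis, hypoxia response, MHC class II, calcium and phosphate transport, the secreted factors and the heat shock list stayed inside, at percentiles of 67.12, 45.65, 83.76, 52.37, 47.86 and 4.48.

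In all, 809 of 7256 eligible genes were higher and 955 lower in pOC than in BMM, of which 229 and 343 differed at least 4-fold. The probe-set disagreement was 0.415 on the log2 scale, and 96.1% of the 849 counted genes with a further probe set above the floor had the same direction there. Neutrophil markers were higher as a list in pOC (median 1.28, in part set by the floor, percentile 100.0), led by Lcn2 at least 9.56-fold, S100a9 at 2.63-fold and S100a8 at 2.6-fold. The stromal list was also higher (median 0.74, percentile 99.27), where 1 of 7 measured members, Dcn, reached 2-fold (8.8 in BMM, 196.1 in pOC), and it moved inside under 3 alternatives.

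**Figure D1:**
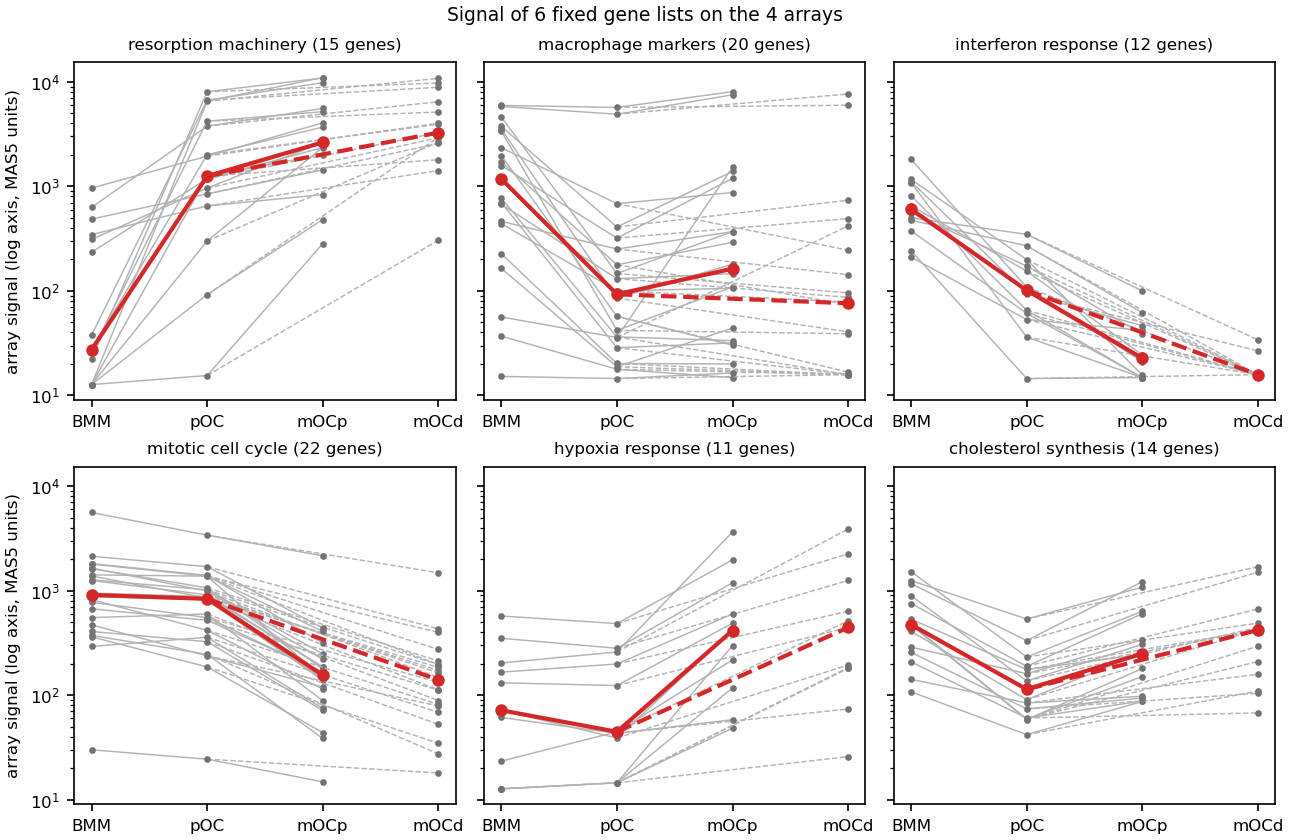
Array intensity (log axis, MAS5 units) of the genes of 6 lists on the 4 arrays, with values under the floor drawn at the floor; grey lines are genes, red points and lines their median, solid towards plastic and dashed towards dentin. Resorption machinery genes are brighter from pOC on, with Ctsk at 22.5 in BMM and 8026.2 in pOC, interferon response genes are dimmer at each stage, and cell cycle genes are dimmer in both mature cultures.

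The comparison of mOCp with pOC followed maturation on plastic. It also spanned 2 further days of culture, and no array separates maturation from time in culture. Hypoxia response, glycolysis and cholesterol synthesis genes were higher in the mature culture, and cell cycle and interferon response genes were lower. Bnip3, a mitophagy receptor induced by low oxygen, was 14.1-fold higher, Calcr, the calcitonin receptor of mature osteoclasts, 18.3-fold, and the scavenger receptor Marco 42.7-fold. Arg1, encoding arginase, read 821.7 against a value under the floor, at least 56.7-fold higher. Cdc20, an activator of mitotic exit, was 9.45-fold lower, and Oasl2, an interferon-induced gene, 12.7-fold lower.

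Of 11 hypoxia response genes 9 were higher (median 2.09, percentile 100.0). Egln3, an oxygen-sensing prolyl hydroxylase, was at least 20.5-fold higher, Ndrg1 10.7-fold, Vegfa 4.87-fold and Pdk1 4.24-fold. Glycolysis genes were higher for 5 of 11 and lower for 0 (median 0.93, percentile 99.99), including the glucose transporter Slc2a1 at 4.07-fold and Pfkl at 4.94-fold. Cholesterol synthesis genes were higher for 10 of 14 (median 1.12, percentile 100.0), for example Msmo1 at 3.66-fold, Sqle at 3.19-fold and Cyp51 at 3.08-fold. Cell cycle genes were lower for 19 of 22 (median −2.16, percentile 0.0), with Aurka at 6.73-fold, Mki67 at 5.96-fold and the replication helicase subunit Mcm5 at 4.49-fold. Interferon response genes were lower for 7 of 12 (median −2.08, in part set by the floor, percentile 0.0), such as Usp18 at 6.34-fold, Ifih1 at 4.48-fold and Irf7 at 4.37-fold.

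Resorption machinery was again higher (5 of 15, median 0.76, percentile 99.98), with Oscar at 7.87-fold, Itgb3, the beta chain of the osteoclast vitronectin receptor, at 5.22-fold and Clcn7 at 2.74-fold. V-ATPase subunits (median 0.62, percentile 99.64), lysosomal genes (0.56, percentile 99.69), podosome genes (0.51, percentile 99.21) and oxidative phosphorylation genes (0.49, percentile 98.01) stood apart on the high side by small shifts, in which 1 of 17, 2 of 21, 2 of 18 and 0 of 20 reached 2-fold. The lysosomal, podosome and oxidative phosphorylation calls ended when suffixed probe sets were left out, the last also with the higher floor and with the mean over probe sets. Among the secreted factors 6 of 11 were higher (median 1.10, percentile 100.0), including the sphingosine kinase Sphk1 at 5.01-fold, Igf1 at 3.65-fold and Efnb2, which encodes ephrin-B2, at least 8.08-fold. Cthrc1, a member the study chose, did not reach the 75th percentile on either array. Macrophage markers were higher for 6 of 20 (median 0.53, percentile 99.75), with Adgre1 at 3.73-fold, Cd14 at 3.4-fold and C1qb at 2.51-fold, a call that ended after loess (percentile 95.11).

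Chemokines and cytokines reached percentile 97.18 (up to 99.55 with the mean over probe sets or without suffixed ones), with Cxcl2 8.96-fold, Il1b 4.42-fold and Ccl3 2.78-fold higher and 0 of 17 lower. The RANK and transcription factor list was inside (percentile 45.39), where Jun was 2.17-fold higher and Mitf 2.87-fold lower, as were repressors (95.55), fusion genes (72.76), MHC class II (29.18), calcium and phosphate transport (49.01) and the heat shock list (63.67). Outside the lists the growth arrest ligand Gas6 was 12.1-fold higher, the acute phase protein Saa3 14.3-fold, the apoptosis gene Pmaip1 13.3-fold and the adenylate kinase Ak4 at least 23.2-fold. The 3 other probe sets of Ak4 had log2 ratios from 0.34 to 4.04, against at least 4.54. Rtp4, an interferon-induced gene, was 21.6-fold lower, although its other probe set differed by −0.07 on the log2 scale, and the mitotic kinase Nek2 was 10.5-fold lower. The log2 ratio of −3.4 for Nek2 stood against −2.95 and −0.25 on its other probe sets.

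In all, 633 of 7192 eligible genes were higher and 820 lower in mOCp than in pOC, with 91.8% of counted genes in the same direction on a further probe set. Scaling decided this split: median scaling, which moved the median gene by 0.125, gave 823 higher and 647 lower, and scaling to the spike-ins, which were 0.41 brighter in mOCp on the log2 scale, gave 294 and 1602, so small shifts are relative to the chosen scaling. Lists that stood apart kept their sign under both, while the fusion and chemokine medians, 0.31 and 0.37, turned to −0.10 and −0.04 with the spike-ins. The neutrophil genes Lcn2 (3.03-fold), S100a8 (2.93-fold) and Ngp (2.29-fold) were higher than in pOC, and the dendritic and mast cell list stood apart (median 1.42, percentile 99.82) on 3 measured genes, led by Itgax at 2.67-fold.

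The comparison of mOCd with pOC followed maturation on dentin, the resorbing condition. The same 2 further days of culture lie between these arrays, so maturation, time in culture and dentin cannot be told apart here. Hypoxia response, cholesterol synthesis and resorption genes were higher than in pOC, and cell cycle and interferon response genes lower. Itgb3 was 31.9-fold higher, at 2939.3 against 92.1 (log2 ratio 5.0, but 2.77 on its other probe set), and Calcr 19.7-fold. Rcan2, a regulator of calcineurin, was at least 53.8-fold higher (log2 ratio 5.75, but 3.2 on its other probe set), and Cthrc1 at least 12.4-fold. Ifitm3, an interferon-induced membrane protein, was 15.3-fold lower, and Oas1a, which makes oligoadenylates, 15.9-fold lower.

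Resorption machinery genes were higher for 8 of 15 (median 1.05, percentile 100.0), among them Oscar at 8.8-fold, Ostm1, the partner of Clcn7, at 3.04-fold and the bicarbonate exchanger Slc4a2 at 2.76-fold. Podosome genes were higher for 6 of 18 (median 0.68, percentile 99.94), including Ptk2b at 3.13-fold, Wipf1 at 2.81-fold and vinculin (Vcl) at 2.77-fold. V-ATPase subunits had a median of 0.70 (percentile 99.98) with 2 of 17 at 2-fold, Atp6v1e1 and Tcirg1. Lysosomal genes had a median of 0.42 (percentile 98.43), with Hexa and Mcoln1 higher and Ctss and Lamp1 lower, and oxidative phosphorylation genes 0.42 (percentile 97.91) with 0 of 20 at 2-fold. Both of these calls ended after loess and when suffixed probe sets were left out, the lysosomal one also after quantile normalization.

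The hypoxia list held 9 of 11 higher (median 2.22, percentile 100.0), with Bnip3 at 15.0-fold, Vegfa at 11.5-fold and Ndrg1 at 4.98-fold. Glycolysis genes were higher for 4 of 11 (median 0.83, percentile 99.97), such as Slc2a1 at 4.65-fold, and cholesterol synthesis genes for 11 of 14 (median 1.52, percentile 100.0), such as Cyp51 at 5.04-fold and Insig1 at 4.72-fold. Of the secreted factors 7 of 11 were higher (median 1.88, percentile 100.0), including Lif at 4.76-fold, Pdgfb at 3.78-fold, Pdgfa at 3.2-fold and Cthrc1, which the study chose. Cell cycle genes were lower for 21 of 22 (median −2.36, percentile 0.0), with Kif11 at 8.96-fold and Ccnb2 at 7.3-fold. Interferon response genes were lower for 7 of 12 (median −2.41, set by genes at the floor in mOCd, percentile 0.0), with Irf7 at least 17.1-fold, Ifih1 at least 10.9-fold and Ddx58 10.2-fold lower, the last on probe sets that differed in direction.

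Macrophage markers had a median of −0.36 (percentile 2.68), with Msr1 2.78-fold, Fcgr3 2.4-fold and C1qc 2.1-fold lower and Marco 11.7-fold higher, and stood apart after quantile or loess normalization and with the lower floor (percentile down to 0.06). Chemokines and cytokines lay at percentile 3.13 (1.31 after loess, which stands apart), with Ccl5 at least 10.6-fold, Ccl6 2.65-fold and Ccl2 2.62-fold lower and Cxcl2 5.16-fold higher. Also inside were the RANK and transcription factor list (92.81; Traf6 2.58-fold higher, Myc 2.37-fold lower), repressors (79.42; median 0.23, turning to −0.05 with the spike-ins; Id2 5.09-fold higher), fusion genes (86.2), MHC class II (3.23, but 0.53 with the mean over probe sets), calcium and phosphate transport (73.85) and the heat shock list (83.81, but 98.22 with the lower floor). Outside the lists, the autophagy gene Map1lc3a was 13.1-fold higher, the sialyltransferase St8sia6 13.9-fold and the secreted follistatin-like Fstl1 at least 27.4-fold, and galectin-9 (Lgals9) was 10.2-fold lower.

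In all, 779 of 7230 eligible genes were higher and 886 lower in mOCd than in pOC, with 89.1% of counted genes in the same direction on a further probe set. Scaling to the spike-ins, 0.28 brighter in mOCd, gave 494 higher and 1420 lower, and median scaling, a shift of 0.114, gave 944 and 750. The 3′ to 5′ signal of the transferrin receptor control was 0.685 higher in mOCd than in pOC on the log2 scale. The neutrophil gene Ngp was 2.26-fold and the dendritic cell gene Itgax 2.98-fold higher than in pOC. This comparison shares the pOC array with that of mOCp, so the surfaces are compared directly in what follows.

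**Figure D2:**
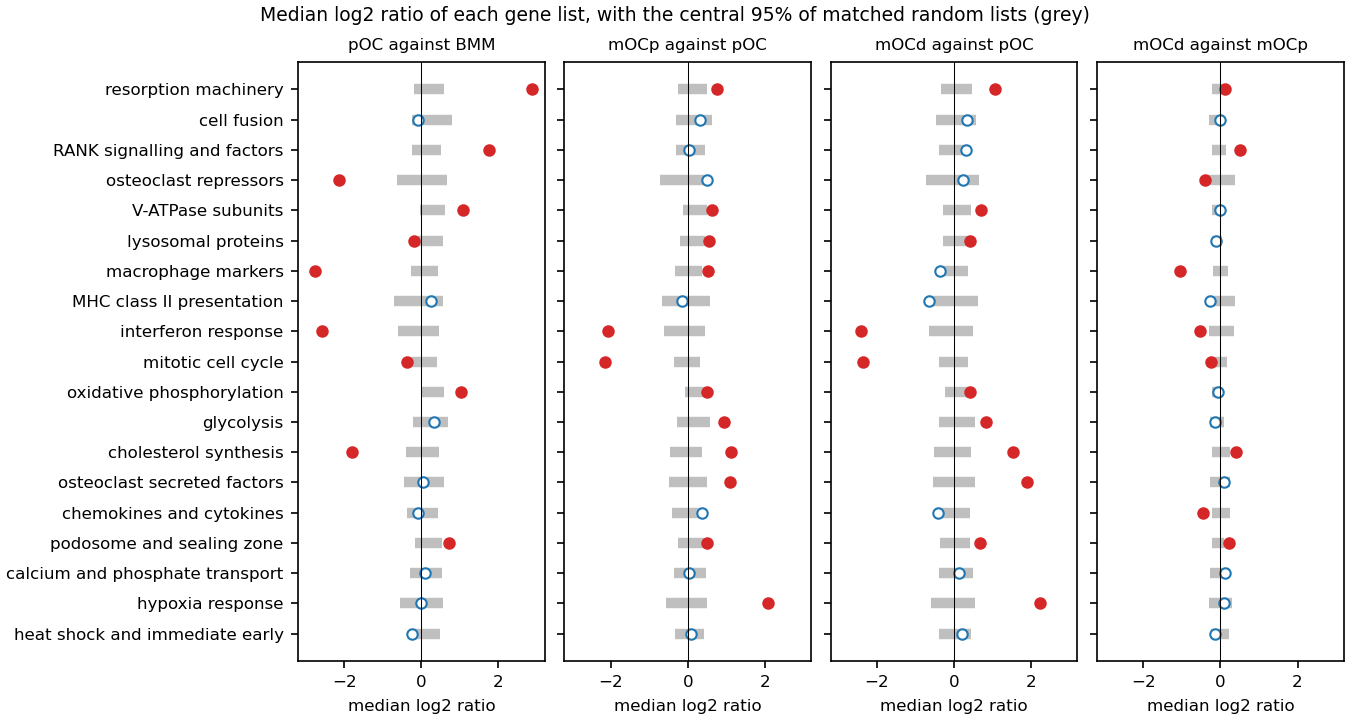
Median log2 ratio of 19 gene lists in the 4 comparisons; grey bars span the central 95% of 10000 matched random lists, red filled points lie at or beyond it and blue open points inside. Macrophage markers lie at −2.75 in pOC against BMM and at −1.04 in mOCd against mOCp, and the hypoxia list at 2.09 and 2.22 in the mature cultures against pOC and at 0.09 between them.

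The comparison of mOCd with mOCp asked what distinguished osteoclasts resorbing dentin from those on plastic. Cthrc1 was 6.81-fold higher on dentin (179.9 against 26.4, log2 ratio 2.77), the highest ratio among genes measured above the floor on both arrays by the rule for named genes. Dock6, a guanine nucleotide exchange factor that was under the floor on plastic, had the higher bound of at least 7.67-fold. Itgb3 was 6.11-fold higher on dentin and Rcan2 5.14-fold. In each case the other probe set was higher by less, with log2 ratios of 1.19 against 2.61 for Itgb3 and 1.61 against 2.36 for Rcan2. Macrophage markers were lower on dentin, led by C1qc at 4.44-fold, and chemokines were lower too, led by Ccl5 at least 19.7-fold. Arg1, which is on neither list, was 9.33-fold lower.

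Macrophage markers were lower for 8 of 20 and higher for 0 (median −1.04, in part set by the floor, percentile 0.0). After C1qc came the Fc receptor Fcgr3 (3.94-fold lower), C1qb (3.85-fold) and the scavenger receptor Marco (3.64-fold), and Adgre1 was 2.42-fold lower, while Csf1r read 7511.7 on plastic and 7644.1 on dentin. Chemokines and cytokines were lower for 4 of 17 (median −0.45, percentile 0.03): Ccl5, the interleukin-1 receptor antagonist Il1rn (3.12-fold), Ccl2 (2.54-fold) and Ccl6 (2.45-fold). Interferon response genes were lower by a median of −0.52, set by genes at the floor on dentin (percentile 0.07), with 1 of 12 counted as lower (Ddx58, 2.93-fold), a call that ended with the higher floor. Cell cycle genes had a median of −0.25 (percentile 0.18) with 0 of 22 at 2-fold.

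The RANK signalling and transcription factor list was higher on dentin (median 0.51, percentile 100.0), although 0 of 16 reached 2-fold. Nfatc1 read 3330.6 on dentin and 1971.8 on plastic, Ppargc1b 1156.5 and 593.1, and Traf6 322.7 and 174.8. Repressors of osteoclast formation were lower as a list (median −0.41, percentile 1.18), although 0 of 7 were counted as lower. Id1, too dim to be counted, read 24.3 on dentin and 58.2 on plastic, but Id2, an inhibitor of transcription factor binding, was 3.93-fold higher on dentin. Podosome genes had a median of 0.22 (percentile 99.97), cholesterol synthesis genes 0.40 (percentile 99.93) and resorption machinery 0.11 (percentile 98.16), with 1 of 18, 0 of 14 and 1 of 15 at 2-fold, the 1 being Itgb3 in both lists. Leaving out suffixed probe sets ended the cholesterol, resorption and repressor calls, and averaging probe sets ended the podosome call (percentile 64.96).

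The secreted factors went both ways and were inside (median 0.09, percentile 80.2), except with the higher floor (0.42, percentile 99.78): Cthrc1, Pdgfa (2.66-fold), Vegfa (2.36-fold) and the cytokine Lif (2.22-fold) were higher on dentin and Igf1 was 2.76-fold lower. Hypoxia (73.56), glycolysis (29.51), oxidative phosphorylation (68.46), V-ATPase (92.34), lysosomal (23.94), fusion (78.94), MHC class II (5.1), calcium and phosphate transport (88.66) and heat shock genes (12.04) were inside. Among their members Cd9, a tetraspanin of the fusion list, was 2.08-fold, Ndrg1 of the hypoxia list 2.14-fold and the lysosomal protease Ctss 2.02-fold lower. The immediate early gene Egr1 was 3.51-fold higher, and Vegfa, higher by 2.36-fold, is also on the hypoxia list. V-ATPase subunits stood apart on the high side after quantile or loess normalization (percentile up to 99.23). Outside the lists the adhesion receptor P-selectin (Selp) was 6.66-fold higher, the adenylate kinase Ak5 6.45-fold and Tspoap1 4.84-fold. The log2 ratio of 2.73 for Selp stood against 0.41 and 1.35 on its other probe sets, and that of 2.69 for Ak5 against 1.58. Tmem86b was 6.62-fold higher, but its other probe set had a log2 ratio of −0.23. Rnase4 was 5.86-fold lower on dentin, the complement factor Cfb at least 7.04-fold, the transcription factor Max 4.9-fold and Pmaip1 4.24-fold.

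In all, 149 of 6915 eligible genes were higher on dentin and 176 lower, 14 and 12 of them at least 4-fold, and under spike-in scaling 230 and 130. The probe-set disagreement was 0.461, and of counted genes with a further probe set 84.6% had the same direction there and 40.9% also reached 2-fold. The 3′ to 5′ signal of the transferrin receptor control was 0.86 higher in mOCd than in mOCp on the log2 scale. Of other cell types, Dcn was 2.31-fold higher on dentin, and the neutrophil genes Lcn2 (3.58-fold) and S100a8 (2.2-fold) were lower.

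**Figure D3:**
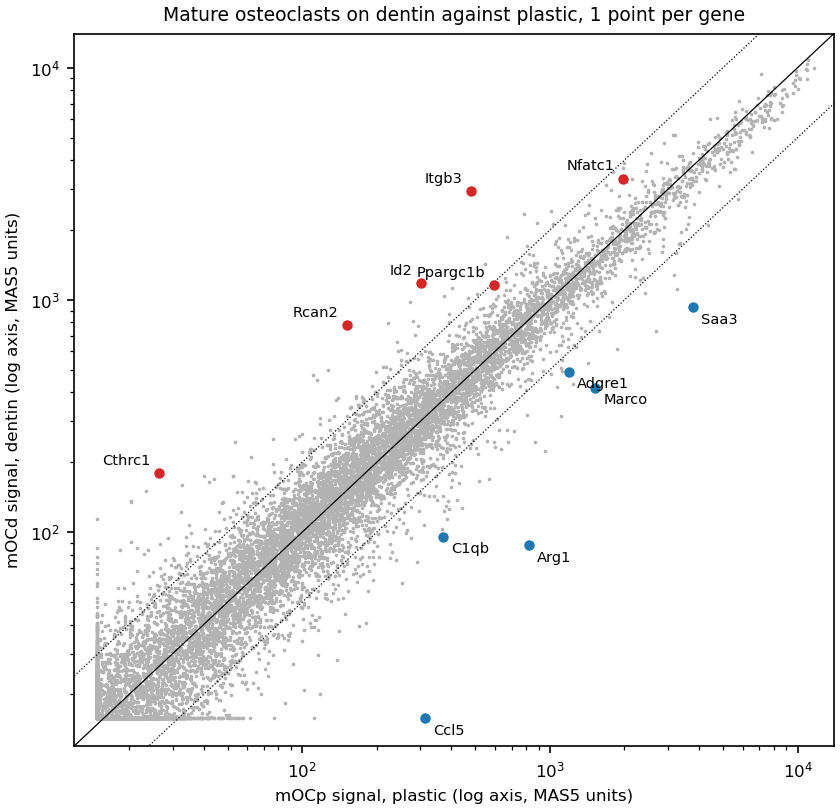
Intensity on dentin (mOCd) against plastic (mOCp), both on log axes in MAS5 units, 1 point per gene with values under the floor drawn at the floor; the solid line marks equality and the dotted lines 2-fold. Cthrc1 lies at 26.4 on plastic and 179.9 on dentin and Itgb3 at 480.8 and 2939.3, while Arg1 (821.7 and 88.1) and Ccl5 lie below the lower line; red and blue points are named genes higher or lower on dentin, and Nfatc1 and Ppargc1b are under 2-fold.

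Markers of further cell types gave no list apart beyond those named. Erythroid, B cell, T and NK cell and endothelial markers were inside in all 4 comparisons, with 3, 5, 3 and 2 genes measured, and the B cell gene Ighm read 279.6 in BMM and 37.2 in pOC. The stromal list was inside in mOCp and mOCd against pOC and in mOCd against mOCp (percentiles 42.56, 8.27 and 96.78), although each stood apart under at least 1 alternative (1.76, 0.67 and 98.53), the neutrophil list likewise (93.19, or 98.59 with the spike-ins, 25.24 and 37.25), and the dendritic and mast cell list in pOC against BMM, mOCd against pOC and mOCd against mOCp (48.45, 75.14 and 16.3). Over the 26 lists and 4 comparisons 46 of 104 medians stood apart, against 5.2 for lists drawn at random.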

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

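The tests of the macrophage pattern, the test of probe-set disagreement and the test of the absolute level of oxidative phosphorylation genes were chosen only after the result was seen, and the others before.

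Macrophage markers had a median log2 ratio against pOC of 0.53 on plastic and −0.36 on dentin, and chemokines and cytokines of 0.37 and −0.42, opposite directions on the 2 surfaces. These differences were not tested, since each surface has 1 array and both ratios share the pOC array. The chemokine value on plastic turned to −0.04 under spike-in scaling. There was 1 gene at least 2-fold higher on plastic and 2-fold lower on dentin than pOC, C1qc (log2 ratios 1.08 and −1.07). Outside the gene comparisons, the 3′ probe set of the 18S ribosomal RNA control was 2.53-fold brighter in mOCp and 2.0-fold brighter in mOCd than in BMM. It read 117.2 in BMM, 108.3 in pOC, 297.0 in mOCp and 234.7 in mOCd, so the rise also falls on the comparisons of the mature cultures with pOC. Among the 9160 probe sets that are unnamed here, 121 were at least 4-fold higher and 61 lower in mOCd than in BMM.

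For Cthrc1 and the other genes that differ between dentin and plastic, scaling is argued against as the source of the Cthrc1 ratio, whose lowest log2 value was 2.74 under median, quantile and loess scaling. These scalings moved the median gene by only −0.012, −0.008 and −0.015, so the result speaks to scaling of whole arrays and not to error in this probe set. Stromal or osteoblast cells rich in collagen are argued against by Col1a1, Col1a2 and Col3a1, of which 0 of 3 reached the 75th percentile of the mOCd array (15.0, 10.3 and 8.3). Stromal cells of another kind stay open, since Dcn was 2.31-fold higher on dentin and the stromal list reached percentile 96.78, or 98.53 without suffixed probe sets. Dcn was, however, counted as lower in mOCp than in pOC and was not counted as higher in mOCd than in pOC. A smaller share of differentiated cells on dentin would make genes that are higher in pOC than in BMM lower there, but Spearman's rho between these ratios, which share no array, was 0.125 across 13072 genes. RNA quality stays open: the 3′ to 5′ ratios of Gapdh and Actb differed by −0.044 and 0.078, inside the bound of 0.25 set for both beforehand, but that bound left out the transferrin receptor control, which differed by 0.86. Disagreement between probe sets also stays open for the genes as a whole, since 84.6% of counted genes kept their direction on a further probe set, and with 1 array each the surface itself, untested as the biological explanation, cannot be told apart from variation between RNA samples or arrays.

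For the lower macrophage markers on dentin, a constant share of macrophages like the BMM sample on plastic is argued against as their only source. Among the list members counted as lower, without Marco, the share of BMM signal needed to fill the gap between the surfaces ran from 2.08% for C1qa to 48.8% for Itgam. The range between the 10th and 90th percentiles was 14.4-fold. This takes the signal of the osteoclasts themselves as equal on both surfaces. A small share of such macrophages beside another source therefore stays open, as C1qa, C1qc and C1qb needed 2.08%, 3.96% and 5.93%. For all genes lower on dentin the test leaves such a share undecided. Of these, 64.2% (113 of 176) were brighter in BMM than in mOCp, but the share over all genes was not computed. Under the same assumption, the genes dimmer in BMM would need another source. The 0 of 4 found for Arg1, Marco, Saa3 and Ccl5 cannot speak for the others because these were picked after their values were seen. Scaling is argued against by a median closest to zero of −0.91 under median, quantile, loess and spike-in scaling. Spike-in scaling, the largest of these shifts, moved the median gene by 0.132, so the result speaks only to scaling of whole arrays. Disagreement between probe sets stays open: 80.0% of 15 further probe sets of the list (12, from 9 of its 20 genes) had the direction of the main one, and the 100.0% among genes already counted as lower rests on 6 probe sets of 3 genes. Macrophages in another state than the BMM sample, RNA quality and a response of the osteoclasts to dentin also stay open, and that fewer such macrophages persist on dentin may be held only as a hypothesis.

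Oxidative phosphorylation genes in mOCp against pOC had a median log2 ratio of 0.49, close to the 0.41 by which the spike-ins were brighter in mOCp. The list was at percentile 98.14 among matched lists after loess. The call ended under 3 other alternatives, with a lowest percentile of 93.41. The random lists are matched on intensity, so a scaling by array or by intensity moves them and the list nearly together. The percentile after loess therefore cannot decide whether scaling is the source of the shift. The median was 0.08 after scaling to the spike-ins, but these are hybridisation controls and do not measure mRNA per cell, so that value cannot decide the absolute level. Whether the genes differ in absolute level stays open, and a higher share of RNA per array and a higher level per cell cannot be told apart.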

How the results depend on the processing

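The scaling to the spike-ins was chosen only after the control probe sets had been seen, and the other 8 alternatives were planned. The alternative without a minimum for the brighter array applies to counts only. Under the other 8, 0 of the 114 ratios of genes named for their size or brightness changed sign where a value existed. The same held for 0 of the list medians that stood apart. The 114 were chosen for large ratios, so a change of sign was unlikely from the start. Ratios of list members outside the 114 were not checked singly. The log2 ratio of Cthrc1 in mOCd against mOCp ran from 2.74 (loess) to 2.90 (spike-ins). Counts of genes at least 2-fold higher or lower stayed within 1.5 times the reported ones under median, quantile and loess scaling and under both other floors. With no minimum for the brighter array, mOCd against mOCp gave 319 genes higher and 331 lower, because dim genes were then counted. With the mean over all probe sets, 522 genes were lower in mOCp than in pOC, of which 492 were among the 820 reported, and the cause was not tested. Under spike-in scaling, mOCp against pOC gave 294 higher and 1602 lower, mOCd against pOC 494 and 1420, and mOCd against mOCp 230 higher, since that scaling shifts every gene by −0.412, −0.28 and 0.132. Median scaling moved the median gene by 0.125 and 0.114 in mOCp and mOCd against pOC, and spike-in scaling by 0.077 in pOC against BMM.

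Of the 46 list medians that stood apart, 32 did so under every alternative run for lists, and of the 58 inside, 12 stood apart under at least 1 of these. Of the 114 ratios of genes named for their size or brightness, 24 moved by more than the probe-set disagreement with the 40th percentile as floor and 45 with the 60th. These were chiefly lower bounds, which depend on the floor by construction. With the mean over probe sets 33 moved, and without suffixed probe sets 7 of the 98 that still had a value. Signal over background limits what can be read: 10676 to 11158 genes exceeded the floor per array, and ratios with a value at or under it are bounds. Ratios with a value just above the floor are given as plain folds and are imprecise. Examples are Scin, at 13.4 in BMM with a floor of 12.7, and Calcr, at 15.5 in pOC with a floor of 14.5. No paired analysis was possible because each group has 1 array.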

Other observations

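The counts of mOCd against BMM were added to the planned list medians of this comparison after the other comparisons had been seen, and no explanation was tested in this part.

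Over the whole course from BMM to osteoclasts on dentin, 1419 of 7537 eligible genes were higher and 1532 lower, and 13 of the 26 lists stood apart. The 3′ to 5′ signal of the transferrin receptor control was 0.704 higher in mOCd on the log2 scale. All 15 resorption machinery genes were higher (median log2 ratio at least 7.14, a bound since its middle gene was at the floor in BMM), 14 of 17 V-ATPase subunits (1.95) and 17 of 20 oxidative phosphorylation genes (1.39). Ctsk was 433-fold higher and the metallothionein Mt3 at least 359-fold, the latter reading 372.2 in pOC and 4561.5 in mOCd. Myo1d, an unconventional myosin, was 139-fold higher and Bdh1, a mitochondrial ketone body enzyme, 68.9-fold. On their other probe sets the log2 ratios were 2.61 against 7.11 for Myo1d and 5.69 against 6.11 for Bdh1. All 12 interferon response genes were lower, 10 of them with mOCd at the floor, so that their median of −5.25 is a bound, with Rsad2 at least 114-fold. Outside that list, Rtp4 was at least 171-fold lower, with a log2 ratio of −1.7 on its other probe set. The neutrophil list, markers of another cell type, also stood apart on the high side (median 0.95, percentile 99.58, 4 of 10 higher). The endocytic adaptor Dab2 was 52.7-fold lower, with its 3 other probe sets lower too.

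Some genes were dim in pOC between brighter values in BMM and the mature cultures. Cholesterol synthesis genes, lower in pOC, ended inside in mOCd against BMM (median −0.25, percentile 22.16), with 5 of 14 lower and 0 higher. Msmo1 read 1163.8 in BMM, 332.9 in pOC, 1217.9 in mOCp and 1500.3 in mOCd. Gas6 read 739.8, 88.4, 1072.4 and 1513.8 in the same order. Id2 read 1783.9 in BMM, 232.3 in pOC and 300.7 in mOCp, with 1182.5 in mOCd. The phosphate exporter Xpr1 read 138.6, 1546.4, 3152.5 and 5134.1 over the 4 arrays, and Ank, a transporter tied to pyrophosphate export, 364.2, 2131.8, 2798.7 and 3920.5.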
